A study of Mus musculus with 12 samples.

How the data were processed

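RNA was sequenced from NK cells sorted from mouse lymph nodes. There were 12 libraries, 4 each from tumor-free nodes, nodes of a lymphatic model and nodes of a hematogenous model of diffuse large B cell lymphoma. Groups and replicate numbers were taken from the sample titles in the labels. Per the labels' protocols, nodes were made into single-cell suspensions, NK cells were sorted, and total RNA was extracted from them. Poly(A) RNA was then made into stranded libraries and read as single-end reads of 120 bp.

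The deposited values are raw read counts per gene, 1 file per library, made by the authors before deposit. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.1.0 and HTSeq 2.0.2 were used with the genome build GRCm39. The annotation release, the settings and the strand option of the counting are not given in the sources used here. Antisense and overlapping genes can therefore share reads. Each file held 56748 gene IDs and 5 summary lines. The summary lines name no gene and were left out of library sizes and tests. Reads outside annotated features made up 11.4% to 24.6% of all reads in a library, ambiguous reads 1.55% to 2.12%, unaligned reads 5.51% to 14.6% and reads with several alignments 3.85% to 6.48%. The line for low alignment quality stood at 0 in all 12 libraries. Symbols came from GENCODE M21, which names an older build, so that no coordinates are printed. They matched 52073 gene IDs (91.8%), which held 99.5% of the counts.

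Depth ranged from 6654215 to 43494812 gene counts per library. It was lowest in 3 of the tumor-free libraries, so low genes are measured least precisely there. Counts came from reads without molecular identifiers, so floors cover counting error only. Where a group had 0 counts, a fold is a lower bound against 3 counts over the group.

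Changed genes were called with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood F test was run with robust estimation, TMM scaling and the default expression filter by group. All 12 libraries entered a model of group alone, with 9 residual degrees of freedom, and 16016 genes were tested. The biological coefficient of variation was 0.429. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled and are given as mean and SD of 4 libraries.

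Gene lists, 34 in all, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01. Of these lists 23 were of cell states, 10 of other cell types and 1 of handling and stimulation. Camera with an estimated correlation and fry were run beside it. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Library measures were compared with exact permutation tests, two-sided, for which 0.0286 is the smallest p that 4 against 4 allows.

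Named genes followed a rule for each comparison. It took the 6 higher and the 6 lower genes with the largest fold change among called genes with a mean CPM of at least 5 and groups that did not overlap. Gene models without a proper symbol, immunoglobulin and T cell receptor segments, pseudogenes and sex-linked marker genes were left out of this part. From each list it took up to 3 called genes with the smallest adjusted p. It always took Ncr1, Klrb1c, Gzmb, Prf1, Ifng, Mki67, Pdcd1, Cd79a, Cd3e and Lyz2. Some genes that the rule named are not reported here.

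The gene test was tested on simulated counts for 16016 genes, of which 200 were changed, 100 at 2-fold and 100 at 4-fold. For the lymphatic model against tumor free, 44% of the 2-fold and 66% of the 4-fold changes were recovered, with 2 false calls among 112. For the hematogenous model these values were 38% and 61%, with 6 false calls among 105. Between the models they were 43% and 62%, with 7 among 112. In 20 simulations of the lymphatic comparison over 16016 genes, 3 lists changed at 2-fold were recovered in 100% of cases. Genes were drawn independently and all members of these lists were changed alike. The recovery therefore does not bear on the choice between a preset and an estimated correlation.

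Alternatives covered other scalings (DESeq2 size factors, upper quartile, library size alone), other filters on low counts, DESeq2 1.42.0, voom with quality weights, estimation without robustness and fits of the 2 compared groups alone. They also covered a replicate block, removal of B cell and immunoglobulin genes, a B cell covariate, stricter thresholds and leaving out each library in turn. Equal depth, with every library thinned to 6654215 counts, and removal of the gene length trend were chosen after seeing the data. Exon lengths were held for 97.8% of the tested genes.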

Results

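Gene expression was measured by RNA sequencing of natural killer (NK) cells, the innate lymphocytes that kill virus-infected and malignant cells, sorted from mouse lymph nodes. The 12 libraries fell into 3 groups of 4. One group came from nodes of tumor-free C57BL/6J mice, and the other groups came from tumor-bearing nodes in models of diffuse large B cell lymphoma that had spread through lymphatic vessels (lymphatic group) or through blood vessels (hematogenous group). The question posed by the design was how the transcriptome of NK cells in the node differs between the tumor-free state and each route of spread. The labels number the samples of a group 1 to 4 without saying that they came from separate animals, so the p-values measure the spread between these samples, which may be technical.

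Counts assigned to genes came to 8355021, 6654215, 23674960 and 6803900 in tumor-free replicates 1 to 4. They came to 43494812, 39130676, 17672832 and 24890461 in the lymphatic libraries and to 10087837, 19625766, 15338450 and 13371013 in the hematogenous libraries. Reads outside annotated features made up 21.2% ± 3.00 (SD, n = 4) of all reads in the hematogenous group, against 15.7% ± 1.75 in the lymphatic group (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 allows) and 14.8% ± 4.30 in the tumor-free group (exact p = 0.0857). None of the 33 comparisons of library measures passed after Benjamini-Hochberg adjustment (lowest adjusted exact p = 0.135). With 0.0286 as the smallest exact p, a comparison could pass only if most of the 33 stood at that floor. Not passing is therefore no evidence that the groups were alike. With every library thinned to 6654215 counts, tumor-free replicates 1, 2 and 4 had reads on 14751, 14168 and 14571 genes, tumor-free replicate 3 on 20941 genes, and the other 8 libraries on 16836 to 21886 genes. Genes read in few tumor-free libraries therefore stand beside this difference in detection. In all, 16016 genes were tested.

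In libraries of NK cells sorted from lymphatic-model nodes, mRNA levels of genes induced by type I interferon were higher than in tumor-free nodes (camera adjusted p = 0.0464 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation, were higher as well, but at adjusted p = 0.0743 with an estimated correlation. Usp18, a feedback inhibitor of interferon signalling, rose from 18.9 ± 8.16 to 155 ± 25.4 CPM (gene counts scaled to library size, mean ± SD, n = 4 per group; log2 fold change 3.04, SE 0.286, edgeR adjusted p = 4e-06). Fos, a subunit of the AP-1 transcription factor, rose from 7.22 ± 2.98 to 390 ± 101 CPM (log2 fold change 5.72, SE 0.443, edgeR adjusted p = 1.8e-05). Ifng, which encodes interferon-gamma, rose from 64.7 ± 17.8 to 190 ± 72.4 CPM (log2 fold change 1.56, SE 0.231, edgeR adjusted p = 0.000417), and the proliferation marker Mki67 from 60.1 ± 16.9 to 160 ± 46.9 CPM (log2 fold change 1.41, SE 0.236, edgeR adjusted p = 0.00153). In all, 439 genes changed, 372 higher and 67 lower, and 243 of them changed at least 2-fold. With the mean of the B cell list as a covariate 207 genes changed, and with B cell and immunoglobulin genes removed 437 did. The covariate, centered over all libraries, ran from −1.25 to 0.211 in the tumor-free and from −0.137 to 1.34 in the lymphatic libraries. As it moved with the group, calls lost with it cannot show that B cells gave the changes. Lists of B cell and erythroid genes passed camera as higher and that of stroma and endothelium as lower (adjusted p = 0.00442, 0.00375 and 0.0119). None of these lists passed with an estimated correlation (adjusted p = 0.622, 0.28 and 0.0962). By the rule for named genes (mean CPM of at least 5, groups that did not overlap), the largest rises also took in Atf3, a stress-induced transcription factor gene, at 5.66 (SE 1.19) and the interferon-induced gene Ifi44 at 4.39 (SE 0.843). By the same rule the largest falls took in Tgfb3, which encodes a transforming growth factor, at −1.46 (SE 0.312), S100a4 at −1.37 (SE 0.301) and Rnaseh2c, a subunit gene of ribonuclease H2, at −1.34 (SE 0.254).

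**Figure D1:**
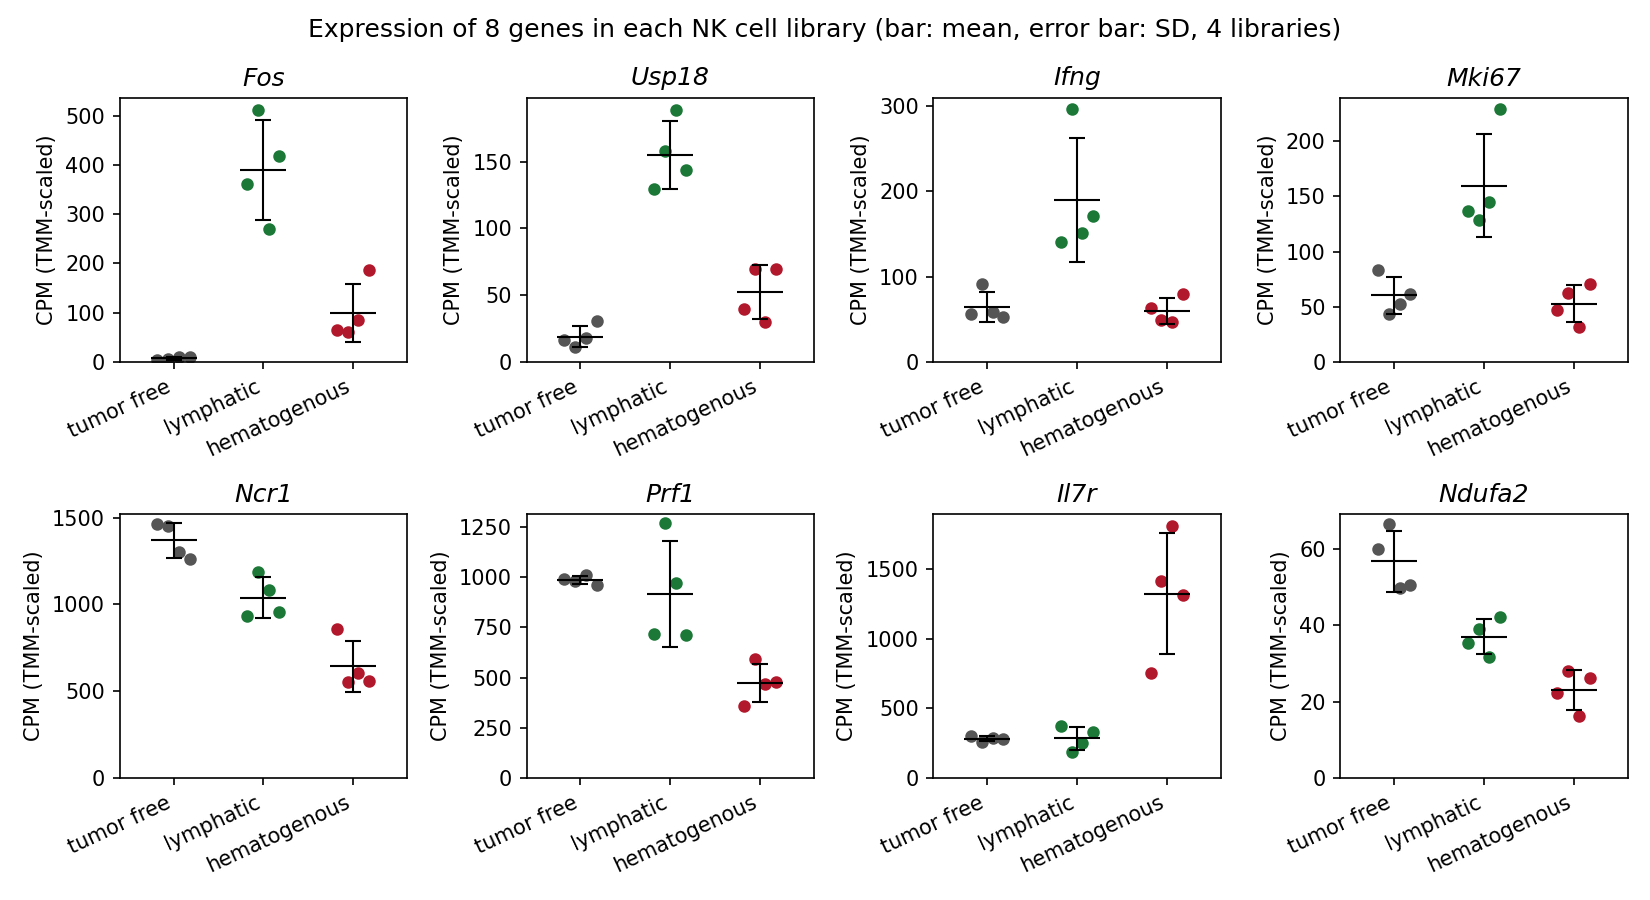
CPM (TMM-scaled counts, linear axis from 0) of 8 genes in each of the 12 libraries; each point is a library, and the bar and error bar are the mean and SD of the 4 libraries of a group. Fos, Usp18, Ifng and Mki67 had their highest group mean in the lymphatic libraries, Il7r had its highest in the hematogenous libraries, and Ncr1, Prf1 and Ndufa2 had their lowest there.

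Of the 41 tested members of the type I interferon list, 36 rose and none fell (41 adjusted over the list alone). The median log2 fold change was 2.1. Oas2, a sensor that activates RNA decay, rose by a log2 fold change of 5.81 (SE 0.763) and Slfn5 by 2.22 (SE 0.207). The list passed camera (adjusted p = 3.19e-62, and adjusted p = 0.0464 with an estimated correlation). Ifit1bl1, at 2.16 (SE 0.206), has near-identical neighbours in its family, so reads may be split among them. In the list of interferon-gamma response genes 10 of 35 rose (18 adjusted over the list alone). They included the GTPases Gbp9 at 1.43 (SE 0.13), Irgm1 at 1.09 (SE 0.133) and Gbp6 at 2.17 (SE 0.31), which also belong to families of similar sequence. It passed camera (adjusted p = 7.02e-10, but adjusted p = 0.226 with an estimated correlation).

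The list of immediate early and heat shock genes, fixed as a sign of tissue handling as well as of stimulation, held 15 risen genes of 24 tested (20 adjusted over the list alone). Its median was 1.08. Fosb rose by 8.37 (SE 1.05), the phosphatase gene Dusp1 by 4.87 (SE 0.43), Jun by 3.17 (SE 0.308) and Zfp36, whose product destabilizes cytokine mRNA, by 1.61 (SE 0.139). The camera adjusted p was 1.01e-22, and the adjusted p was 0.0743 with an estimated correlation. Among inhibitory receptors and exhaustion-linked genes 7 of 25 rose (9 higher and 1 lower adjusted over the list alone). The orphan nuclear receptor genes were among them, Nr4a2 at 4.06 (SE 0.354) and Nr4a1 at 3.84 (SE 0.435). The list passed camera (adjusted p = 0.0143, but adjusted p = 0.463 with an estimated correlation). Pdcd1, the gene of the checkpoint receptor PD-1, stood at 0.164 ± 0.128 CPM against 0.853 ± 1.02 (log2 fold change −2.29, SE 1.26, edgeR adjusted p = 0.464). In the activation list 6 of 19 rose (9 adjusted over the list alone). Among them were the early activation marker Cd69 at 1.41 (SE 0.228) and the transcription factor genes Myb at 1.42 (SE 0.169) and Irf8 at 1.34 (SE 0.231). Its camera adjusted p was 4.9e-05, and its adjusted p was 0.0743 with an estimated correlation.

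Cell cycle genes of G2 and M rose in 6 of 30 cases (13 adjusted over the list alone; median 1.17). Cenpa, the centromeric histone, stood at 1.34 (SE 0.208) and the mitotic kinesin gene Kif11 at 2.19 (SE 0.411). That list passed camera (adjusted p = 3.01e-16, but adjusted p = 0.076 with an estimated correlation). The G1 and S list also passed (camera adjusted p = 7.36e-05, but adjusted p = 0.463 with an estimated correlation), although only Mcm6 of its 26 genes was called. The chemokine genes Ccl3 and Ccl4 rose by 1.96 (SE 0.28) and 2.62 (SE 0.422). Their list of 14 effector cytokines and chemokines, with 3 risen genes (5 higher and 1 lower adjusted over the list alone), did not pass (camera adjusted p = 0.123). Of 26 unfolded protein response genes 4 rose (4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0831). The chaperone genes Dnajb9 and Hspa5 rose by 1.67 (SE 0.228) and 1.05 (SE 0.192). Glycolysis (Gapdh, a gene with many pseudogene copies, at 1.08, SE 0.189; 1 of 20 higher, or 2 higher and 1 lower adjusted over the list alone) and MYC and ribosome biogenesis genes (Slc3a2 at 0.81, SE 0.154, and Tfrc at 1.06, SE 0.241; 2 of 28 higher, or 8 adjusted over the list alone) passed camera at adjusted p = 0.0487 and 0.00917, but at adjusted p = 0.546 and 0.622 with an estimated correlation.

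Lower in the lymphatic libraries was a list of genes of tissue-resident group 1 innate lymphoid cells and of a transforming growth factor beta imprint. In that list of 23 genes 5 fell and 2 rose (6 and 2 adjusted over the list alone). The integrin gene Itga1, a residency marker, fell from 64.1 ± 9.91 to 24.1 ± 5.57 CPM (log2 fold change −1.41, SE 0.199) and Zfp683, which encodes the residency factor Hobit, from 17.6 ± 8.94 to 2.48 ± 1.01 CPM (−2.83, SE 0.46). Rgs2 rose by 1.70 (SE 0.236). The list passed camera (adjusted p = 3.97e-05, and adjusted p = 0.0459 with an estimated correlation). Among the 20 NK receptor and identity genes only Klrb1c, which encodes NK1.1, was called, falling by 0.54 (SE 0.137; 2 fell adjusted over the list alone). That list passed camera as lower (adjusted p = 0.000541, but adjusted p = 0.163 with an estimated correlation). Ncr1, the gene of the activating receptor NKp46, had a log2 fold change of −0.40 (SE 0.14, edgeR adjusted p = 0.166). The migration and adhesion list passed as lower with none of its 23 genes called (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0096, but adjusted p = 0.167 with an estimated correlation). Cytotoxic granule genes did not pass (camera adjusted p = 0.225), with 1 of 18 called in each direction, also adjusted over the list alone. These were Serpinb6b at 0.88 (SE 0.217) and Tnfsf10 at −0.53 (SE 0.14). Their median (−0.07) and mean (0.07) differed in sign. Granzyme B (Gzmb) stood at 1.11 (SE 0.444, edgeR adjusted p = 0.285) and perforin (Prf1) at −0.11 (SE 0.168, edgeR adjusted p = 0.863).

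Lists of other cell types had medians on both sides of 0, from −1.96 for stroma and endothelium to 2.71 for erythroid and platelet genes, the same with a gene at 0 counts in a whole group set at its bound. In the B cell list Pax5 alone of 30 genes was called (1.44, SE 0.361; 4 adjusted over the list alone). By camera the list passed (adjusted p = 0.00442, but adjusted p = 0.622 with an estimated correlation). Cd79a averaged 21.3 ± 11.8 CPM in the lymphatic and 10.1 ± 5.78 CPM in the tumor-free libraries (edgeR adjusted p = 0.217). Hba-a2, an alpha globin gene with a near-identical copy, had 0 counts in all tumor-free libraries. It was at least 34.2-fold higher in the lymphatic libraries, counting 3 reads over the tumor-free group as the floor. This and the other bounds against 0 tumor-free counts cover counting error only. Most tumor-free libraries had reads on fewer genes at equal depth, and missed detection may enter the bounds. Hba-a2 was the called gene of its list. This erythroid and platelet list passed camera with 1 of 6 genes called (3 adjusted over the list alone, camera adjusted p = 0.00375, but adjusted p = 0.28 with an estimated correlation). The stroma and endothelium list passed as lower (camera adjusted p = 0.0119, but adjusted p = 0.0962 with an estimated correlation), while the single called gene of its 7, Pecam1, rose by 0.54 (SE 0.11; 1 higher and 2 lower adjusted over the list alone). T cell genes did not pass (camera adjusted p = 0.917), and 1 of 20 was called (also adjusted over the list alone). This was Lat, an adaptor gene of T cell receptor signalling, at −0.69 (SE 0.137, edgeR adjusted p = 0.00673), while Cd3e stood at 0.37 (SE 0.353, edgeR adjusted p = 0.742). Macrophage and monocyte genes did not pass (camera adjusted p = 0.166), and 2 of 21 rose and none fell (3 higher and 2 lower adjusted over the list alone). The lectin gene Clec4a3, at 0 counts in all tumor-free libraries, was at least 18.3-fold higher, and Cd68 rose by 1.60 (SE 0.361, edgeR adjusted p = 0.0164). Lyz2, a lysozyme gene of macrophages, stood at −0.46 (SE 0.393, edgeR adjusted p = 0.699). Group 2 and 3 innate lymphoid genes did not pass (camera adjusted p = 0.412), with 2 of 14 higher (also adjusted over the list alone). These were Kit at 0.78 (SE 0.201) and Il23r, at least 12.7-fold higher than its 0 counts in tumor-free libraries.

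Of the 34 lists, 15 passed camera for the lymphatic model, 11 higher and 4 lower, and 2 passed with an estimated correlation. The number of changed genes was 255 without lymphatic replicate 4, 207 with the mean of the B cell list as a covariate and 729 with DESeq2. Scaling by library size alone gave 295 higher and 108 lower genes (73.2% higher against 84.7%), and removal of the gene length trend, chosen after seeing the data, gave 288 and 150 (65.8% higher). The glycolysis list was lost without any of 7 libraries (tumor-free 3 and 4, lymphatic 2, hematogenous 1 to 4; highest camera adjusted p = 0.316). The MYC list was lost without tumor-free replicate 3 or lymphatic replicate 2 (camera adjusted p = 0.0758 and 0.732) and the inhibitory receptor list without tumor-free replicate 3 or 4 (camera adjusted p = 0.105 and 0.0515). The B cell list was lost without lymphatic replicate 1 and the stroma list without lymphatic replicate 2 (camera adjusted p = 0.21 and 0.0552). Single-gene calls lost without a library were those of Pecam1 (lymphatic 4, edgeR adjusted p = 0.0606), Hba-a2 (lymphatic 3, edgeR adjusted p = 0.0581), S100a4 (tumor-free 2 or lymphatic 3, highest edgeR adjusted p = 0.0658) and Ifi44 (tumor-free 1 or 4, highest edgeR adjusted p = 0.0798). The same held for Atf3 (tumor-free 2 or 4 or lymphatic 2, highest edgeR adjusted p = 0.0818), Tfrc (tumor-free 1 or 2 or lymphatic 2, highest edgeR adjusted p = 0.107) and Mcm6 (tumor-free 2 or 4 or lymphatic 2 or 4, highest edgeR adjusted p = 0.124). Klrb1c was lost without tumor-free 1 or 2 or lymphatic 1, 3 or 4 (highest edgeR adjusted p = 0.115), and Tnfsf10 without tumor-free 1, 3 or 4 or lymphatic 1, 2 or 4 (highest edgeR adjusted p = 0.15). Pax5 was lost without any of 7 libraries (tumor-free 1, 2 and 4, lymphatic 1, hematogenous 2, 3 and 4; highest edgeR adjusted p = 0.203) and Serpinb6b without any of 9, all but lymphatic 3 and hematogenous 1 and 2 (highest edgeR adjusted p = 0.184). Cd68 was lost without lymphatic 1, 2 or 4 (highest edgeR adjusted p = 0.0798), Kit without any of 7 libraries (tumor-free 1, 2 and 4, lymphatic 1 and 4, hematogenous 2 and 3; highest edgeR adjusted p = 0.189) and Il23r without any of 9, all but lymphatic 2 and hematogenous 1 and 2 (highest edgeR adjusted p = 0.0852). The B cell covariate ended the calls of Rnaseh2c, S100a4, Klrb1c, Tnfsf10, Mcm6, Tfrc, Pax5, Pecam1, Cd68, Kit, Il23r and Nrarp, and voom with quality weights those of Fosb, Atf3, Tfrc, Pax5, Hba-a2, Clec4a3 and Il23r. Serpinb6b and Kit were lost with each other scaling, at equal depth and with the gene length trend removed, Mcm6 with library size alone and in the last of these settings, and Ifi44 without the filter on low counts. Mcm6 and Il23r were lost at equal depth, and Mcm6, Pax5, Clec4a3 and Cd68 in fits of the compared groups alone. The replicate block ended the calls of Tnfsf10 and Il23r (edgeR adjusted p = 0.0723 and 0.079).

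In the hematogenous model, libraries of the sorted NK cells had lower mRNA levels for NK receptor, cytotoxic granule and oxidative phosphorylation lists and higher Il7r than in tumor-free nodes. These lists passed camera, but with an estimated correlation their adjusted p was 0.0521, 0.33 and 0.33, and markers of other cell types and the share of reads assigned to genes (62.0% ± 4.57 against 68.3% ± 2.32, exact p = 0.0286, adjusted exact p = 0.135) moved with the group. Ncr1 fell from 1369 ± 102 to 643 ± 147 CPM (log2 fold change −1.09, SE 0.141, n = 4 per group, edgeR adjusted p = 7.89e-05) and Prf1 from 987 ± 20.4 to 474 ± 95.8 CPM (−1.06, SE 0.17, edgeR adjusted p = 0.000468). Il7r, the interleukin-7 receptor gene, found in other lymphocytes as well as in immature NK cells, rose from 283 ± 19.3 to 1326 ± 437 CPM (2.23, SE 0.221, edgeR adjusted p = 1.35e-05). Ndufa2, a subunit gene of respiratory complex I, fell from 56.7 ± 7.98 to 23.1 ± 5.22 CPM (−1.29, SE 0.192, edgeR adjusted p = 0.000246). In all, 2625 genes changed, 1525 higher and 1100 lower, and 893 changed at least 2-fold. By the rule for named genes (mean CPM of at least 5, groups that did not overlap), the largest rises took in Fosb at 4.81 (SE 0.975), Bend4 at 4.62 (SE 0.795), Csf2rb, the common beta chain of the interleukin-3 receptor family, at 4.12 (SE 0.729) and the small nucleolar RNA gene Snora31 at 3.60 (SE 0.768). By the same rule the largest falls were those of Cd209b, a lectin gene of macrophages, at −5.41 (SE 0.989), Pla2g2d, a secreted phospholipase gene, at −2.86 (SE 0.687), Rps4l at −2.62 (SE 0.714), the Notch target gene Nrarp at −2.33 (SE 0.463), Spin2c at −2.16 (SE 0.404) and the ephrin gene Efnb1 at −2.16 (SE 0.307).

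Of the 20 NK receptor and identity genes, 10 fell and none rose (14 adjusted over the list alone). The median log2 fold change was −0.46. The signalling adaptor genes Tyrobp, at −1.20 (SE 0.141), and Fcer1g, at −1.03 (SE 0.124), fell by amounts near that of Ncr1. Klrb1c fell by 0.52 (SE 0.137) and Klrk1, the gene of NKG2D, chosen after its values were seen, stood at −0.06 (SE 0.115, edgeR adjusted p = 0.791). The list passed camera (adjusted p = 1.58e-09, but adjusted p = 0.0521 with an estimated correlation). Among 18 cytotoxic granule genes 6 fell and 1 rose (9 and 1 adjusted over the list alone). Granzyme A (Gzma) stood at −1.20 (SE 0.176) and the cathepsin gene Ctsw at −0.73 (SE 0.123). This list passed camera (adjusted p = 0.000227, but adjusted p = 0.33 with an estimated correlation). Gzmb stood at −0.47 (SE 0.44, edgeR adjusted p = 0.537). Migration and adhesion genes fell in 10 of 23 cases and rose in 1 (10 and 2 adjusted over the list alone). The chemokine receptor gene Ccr2 stood at −1.03 (SE 0.125) and the integrin gene Itgb7 at −0.78 (SE 0.112). The camera adjusted p was 1.1e-05, and the adjusted p was 0.0521 with an estimated correlation. The 11 Ly49 receptor genes, whose reads can be split among close paralogs, did not pass (camera adjusted p = 0.966), with Klra3 at −0.88 (SE 0.182) among 3 that fell and 1 that rose (3 and 4 adjusted over the list alone). Their median (0.03) was above 0 while camera gave the lower direction. The rise, that of Klra13-ps, was lost with DESeq2 size factors and at equal depth, among other settings (edgeR adjusted p = 0.053 and 0.0506). The fall of Klra1 was lost with upper-quartile scaling and with library size alone, among others (edgeR adjusted p = 0.057 and 0.0574).

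Of 36 oxidative phosphorylation genes, 20 fell and none rose (26 adjusted over the list alone; median −0.56), including Cox6a1 of complex IV at −1.02 (SE 0.173). The list passed camera (adjusted p = 7.62e-14, but adjusted p = 0.33 with an estimated correlation). These genes moved beside a lower share of reads assigned to genes (62.0% ± 4.57 against 68.3% ± 2.32, exact p = 0.0286) and a lower share of counts on ribosomal protein genes (3.74% ± 0.941 against 5.09% ± 0.621, exact p = 0.0571). The share of counts on genes of the mitochondrial genome was 1.01% ± 0.197 against 1.86% ± 0.502 (exact p = 0.0571), and the share on the 20 most counted genes of a library 6.27% ± 0.161 against 7.54% ± 0.519 (exact p = 0.0286). After adjustment none of these differences passed (adjusted exact p = 0.135 for each), which the smallest possible exact p of 0.0286 all but fixed in advance. Glycolysis genes fell in 6 of 20 cases and rose in 1 (8 and 1 adjusted over the list alone). Among them were Ldha at −0.75 (SE 0.167) lower and Pdk1, whose product inhibits pyruvate dehydrogenase, at 0.89 (SE 0.168) higher. Their camera adjusted p was 0.00096, and the adjusted p was 0.417 with an estimated correlation. In the G1 and S list 9 of 26 fell and 1 rose (12 and 1 adjusted over the list alone). The replication helicase gene Mcm3 stood at −0.85 (SE 0.216) and the maintenance methylation factor gene Uhrf1 at −1.44 (SE 0.369). This list passed camera (adjusted p = 0.000102, but adjusted p = 0.516 with an estimated correlation). Of 30 G2 and M genes 1 rose and 1 fell (also adjusted over the list alone), and the list did not pass (camera adjusted p = 0.649; median −0.30). Cenpa rose by 0.95 (SE 0.207, edgeR adjusted p = 0.00425). Top2a stood at −1.07 (SE 0.301, edgeR adjusted p = 0.0214), a call lost without tumor-free 1, 2 or 4 or hematogenous 2 or 3 (highest edgeR adjusted p = 0.0761). Mki67 stood at −0.18 (SE 0.234, edgeR adjusted p = 0.655). Lists of MYC targets (Ran at −0.97, SE 0.187, and Ppat at −1.01, SE 0.21; 7 of 28 lower and 1 higher, 8 and 1 adjusted over the list alone), the unfolded protein response (Calr at −1.02, SE 0.214, and Sdf2l1 at −1.87, SE 0.287; 6 of 26 lower and 2 higher, 10 and 3 adjusted over the list alone) and cholesterol and lipid synthesis (Scd2 at −0.85, SE 0.133, and Fasn at −0.68, SE 0.145; 4 of 27 lower and 1 higher, also adjusted over the list alone) passed camera as lower. Their camera adjusted p values were 0.0014, 0.00527 and 0.0375, and their adjusted p values with an estimated correlation were 0.601, 0.55 and 0.33.

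Type I interferon genes rose in 13 of 41 cases (25 higher and 2 lower adjusted over the list alone; median 0.58). Oas2 rose by 5.45 (SE 0.758) and Slfn5 by 1.67 (SE 0.204), and the list passed camera (adjusted p = 1.1e-05, but adjusted p = 0.55 with an estimated correlation). The interferon-gamma response list was divided, with 7 of 35 higher and 7 lower (9 and 9 adjusted over the list alone; camera adjusted p = 0.16), and its median (−0.03) and mean (0.04) differed in sign. In it Gbp9 rose by 1.03 (SE 0.129) and the immunoproteasome gene Psmb10 was at −1.33 (SE 0.213). Fos rose to 99 ± 59.2 CPM (3.74, SE 0.415), Dusp1 by 3.95 (SE 0.417) and Jun by 1.81 (SE 0.296). The immediate early and heat shock list, with 8 of 24 higher and 1 lower (9 and 3 adjusted over the list alone), did not pass (camera adjusted p = 0.218). Ifng stood at −0.11 (SE 0.228, edgeR adjusted p = 0.795). The cytokine receptor list did not pass (camera adjusted p = 0.293), yet 5 of its 22 genes rose (5 adjusted over the list alone). Among them were Il18rap at 0.77 (SE 0.126) and Il18r1 at 0.75 (SE 0.134), which encode the interleukin-18 receptor. Inhibitory receptor genes went both ways, 9 higher and 4 lower of 25 (also adjusted over the list alone; camera adjusted p = 0.704). They included the ubiquitin ligase gene Cblb at 0.79 (SE 0.129) and the receptor gene Pvrig at −0.97 (SE 0.191). Pdcd1 stood at 1.77 (SE 1.22, edgeR adjusted p = 0.364).

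**Figure D2:**
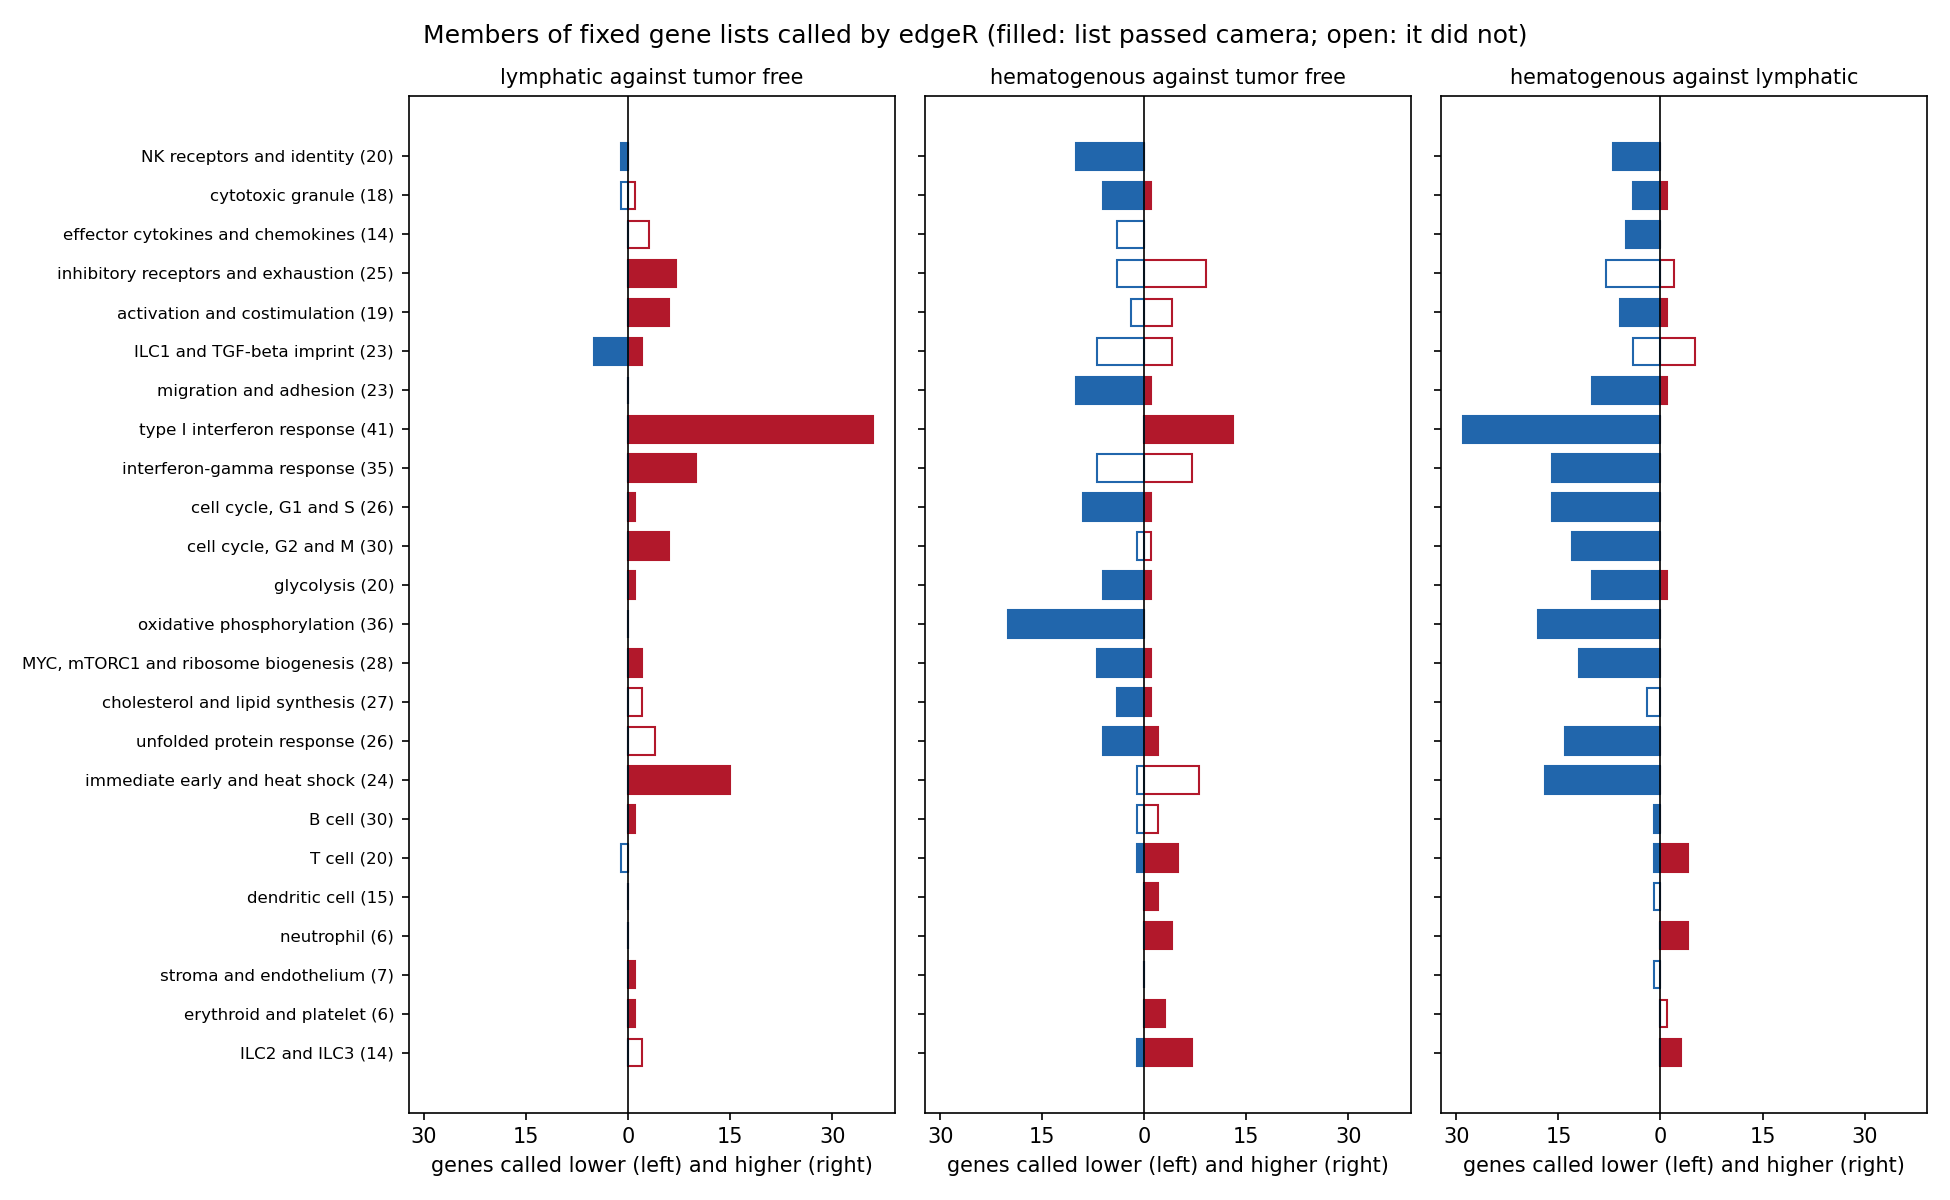
Number of genes called higher (bars to the right) and lower (bars to the left) by edgeR in each fixed gene list that passed camera in at least 1 of the 3 comparisons, with 1 panel per comparison and the number of tested genes beside each list name; filled bars mark lists that passed camera in that comparison and open bars those that did not. In the type I interferon list 36 genes were called higher for the lymphatic model against tumor free, 13 for the hematogenous model against tumor free, and 29 lower for the hematogenous against the lymphatic model.

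Markers of other cell types moved with the hematogenous group. T cell genes rose in 5 of 20 cases and fell in 1 (8 and 2 adjusted over the list alone). Cd8a rose from 18.7 ± 8.09 to 54.2 ± 10.7 CPM (1.53, SE 0.314) and Cd3e from 40.5 ± 24.6 to 101 ± 20.4 CPM (1.30, SE 0.358). By camera the list passed (adjusted p = 0.0173, but adjusted p = 0.55 with an estimated correlation). Genes of group 2 and 3 innate lymphoid cells rose in 7 of 14 cases and fell in 1 (9 and 1 adjusted over the list alone). The transcription factor gene Rora rose by 1.85 (SE 0.335), and Il23r, at 0 counts in every tumor-free library, was at least 41.5-fold higher. Their camera adjusted p was 0.00216, and the adjusted p was 0.33 with an estimated correlation. In the neutrophil list 4 of 6 rose (4 adjusted over the list alone). Csf3r averaged 7.5 ± 4.99 against 0.0955 ± 0.191 CPM, and Il1b was at least 92.1-fold higher than in the tumor-free libraries, which had 0 counts. Bounds against 0 tumor-free counts cover counting error only. Most tumor-free libraries had reads on fewer genes at equal depth, and missed detection may enter these bounds. It passed camera (adjusted p = 0.012, but adjusted p = 0.383 with an estimated correlation). Dendritic cell genes (Tcf4 at 0.67, SE 0.159, and Flt3 at 3.60, SE 1.19; 2 of 15 higher, 1 adjusted over the list alone) and erythroid and platelet genes (Itga2b at 2.91, SE 0.687, and Hba-a2 at least 32.7-fold higher than its 0 counts in tumor-free libraries; 3 of 6 higher, also adjusted over the list alone) passed camera at adjusted p = 0.0342 and 0.0162, but at adjusted p = 0.33 and 0.447 with an estimated correlation. B cell genes did not pass (camera adjusted p = 0.897), with 2 of 30 higher, Pax5 at 1.23 (SE 0.362) and Pou2f2 at 0.76 (SE 0.206), and 1 lower, Cd37 at −0.64 (SE 0.153; also adjusted over the list alone). Cd79a stood at 0.07 (SE 0.406, edgeR adjusted p = 0.936). Macrophage and monocyte genes went both ways, with 6 of 21 higher and 3 lower (6 and 4 adjusted over the list alone), and did not pass (camera adjusted p = 0.397). Clec4a3 was at least 77.9-fold higher than its 0 counts in tumor-free libraries, while Ccr2, at −1.03 (SE 0.125), and the cathepsin gene Ctsd, at −0.76 (SE 0.11), were lower. Lyz2 stood at −0.06 (SE 0.393, edgeR adjusted p = 0.941).

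Of the 34 lists, 15 passed camera for the hematogenous model, 6 higher and 9 lower, and 0 passed with an estimated correlation, where 7 passed fry. With the B cell covariate 1507 genes changed, and with B cell and immunoglobulin genes removed 2633 did. Removal of the gene length trend gave 962 higher and 1464 lower genes (39.7% higher against 58.1%). The cholesterol list was lost without tumor-free replicate 1 or 3 (camera adjusted p = 0.051 and 0.0615), the dendritic cell list without tumor-free replicate 1 or hematogenous replicate 1 (camera adjusted p = 0.0719 and 0.0502), the erythroid list without tumor-free replicate 3 (camera adjusted p = 0.0736) and the T cell list without hematogenous replicate 2 (camera adjusted p = 0.0731). The calls of Cd3e and Klrb1c were lost without tumor-free replicate 2 (edgeR adjusted p = 0.0749 and 0.0537) and that of Rps4l without hematogenous replicate 3 (edgeR adjusted p = 0.0556). Flt3 was lost without any of 11 libraries, all but tumor-free replicate 3 (highest edgeR adjusted p = 0.108), Pax5 without tumor-free 1, 2 or 4 or hematogenous 1 or 3 (highest edgeR adjusted p = 0.0648) and Pou2f2 without hematogenous replicate 4 (edgeR adjusted p = 0.0839). The B cell covariate ended the calls of Klrb1c, Flt3, Top2a and Pou2f2, voom with quality weights those of Fosb, Top2a, Pax5 and Pou2f2, and removal of the gene length trend those of Tcf4, Pax5 and Pou2f2. Cd3e was lost without the filter on low counts and with the replicate block (edgeR adjusted p = 0.102 and 0.0502), and Flt3 in the fit of the compared groups alone.

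Set directly against the lymphatic model, libraries of the hematogenous model had lower mRNA levels in interferon-response, immediate early, cell cycle and chemokine lists and higher Il7r and Txnip. These lists passed camera, but none with an estimated correlation (adjusted p from 0.141 to 0.154). Ifng averaged 59.7 ± 15.2 CPM against 190 ± 72.4 (log2 fold change −1.67, SE 0.231, n = 4 per group, edgeR adjusted p = 0.000321) and Ccl3 45.1 ± 18.5 against 218 ± 93.8 CPM (−2.28, SE 0.282, edgeR adjusted p = 0.000257). Mki67 averaged 52.8 ± 16.9 against 160 ± 46.9 CPM (−1.59, SE 0.236, edgeR adjusted p = 0.000601). Txnip, an inhibitor of thioredoxin and glucose uptake, averaged 2311 ± 884 against 568 ± 57.5 CPM (2.03, SE 0.226, edgeR adjusted p = 6.28e-05), and Il7r differed by 2.21 (SE 0.221, edgeR adjusted p = 4.86e-05). In all, 1417 genes differed, 469 higher and 948 lower in the hematogenous libraries, and 346 differed at least 2-fold. Among the largest differences by the rule for named genes (mean CPM of at least 5, groups that did not overlap) were also Lrp1, an endocytic receptor gene, at 2.18 (SE 0.498), Pik3ip1, a negative regulator of PI3 kinase, at 2.16 (SE 0.343), Itga2b at 2.11 (SE 0.647) and Dmrta1 at 2.06 (SE 0.322). On the lower side stood Rgs16, a regulator of G protein signalling, at −3.93 (SE 0.652), Fosb at −3.56 (SE 0.782), the osteopontin gene Spp1 at −3.20 (SE 0.833) and the replication licensing gene Cdc6 at −3.13 (SE 0.951).

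Type I interferon genes were lower in 29 of 41 cases and higher in none (37 adjusted over the list alone; median −1.27). Phf11b, which has close paralogs that may share its reads, stood at −1.48 (SE 0.214) and Ifit2 at −1.0 (SE 0.147). Interferon-gamma response genes were lower in 16 of 35 cases (22 adjusted over the list alone). The proteasome activator gene Psme1 stood at −0.85 (SE 0.14) and the GTPase gene Igtp at −1.11 (SE 0.196). The camera adjusted p values were 3.08e-31 and 1.55e-13, and the adjusted p values with an estimated correlation were 0.141 and 0.147. Immediate early and heat shock genes were lower in 17 of 24 cases (21 lower and 1 higher adjusted over the list alone). The chaperone gene Hspa8 stood at −1.33 (SE 0.174) and Egr1 at −1.58 (SE 0.272). Their camera adjusted p was 1.24e-15, and the adjusted p was 0.141 with an estimated correlation.

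Cell cycle genes were lower in 13 of 30 G2 and M cases (17 adjusted over the list alone), with the topoisomerase gene Top2a at −2.00 (SE 0.304), and in 16 of 26 G1 and S cases (19 adjusted over the list alone), with the ribonucleotide reductase gene Rrm1 at −1.10 (SE 0.177) and Mcm5 at −1.30 (SE 0.208). Oxidative phosphorylation (18 of 36 lower, 28 adjusted over the list alone; Atp5b at −0.82, SE 0.154, and Atp5a1 at −0.66, SE 0.126), glycolysis (10 of 20 lower and 1 higher, 12 and 1 adjusted over the list alone; Ldha at −1.19, SE 0.168, and Gapdh at −1.07, SE 0.188), MYC targets (12 of 28 lower, 18 adjusted over the list alone; Ran at −1.10, SE 0.187, and Ppat at −1.11, SE 0.208) and the unfolded protein response (14 of 26 lower, 18 lower and 2 higher adjusted over the list alone; Hspa5 at −1.18, SE 0.192, and Calr at −1.25, SE 0.215) were lower as well. All 6 lists passed camera (adjusted p from 1.55e-13 to 1.6e-06), and none with an estimated correlation (adjusted p from 0.141 to 0.205). They moved beside a lower share of reads assigned to genes in the hematogenous libraries (62.0% ± 4.57 against 69.9% ± 2.46, exact p = 0.0286) and a lower share of counts on the 20 most counted genes (6.27% ± 0.161 against 6.85% ± 0.151, exact p = 0.0286), neither of which passed after adjustment (adjusted exact p = 0.135). Both stood at the smallest exact p that the design allows, so that adjustment could hardly be passed. The mitochondrial share was 1.01% ± 0.197 against 1.35% ± 0.363 (exact p = 0.171).

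Among NK receptor and identity genes 7 of 20 were lower (9 lower and 1 higher adjusted over the list alone). The granule membrane gene Nkg7 stood at −0.86 (SE 0.126), Tyrobp at −0.82 (SE 0.14) and the transcription factor gene Eomes at −0.65 (SE 0.125). Ncr1 stood at −0.69 (SE 0.14, edgeR adjusted p = 0.00482, but −0.47 and edgeR adjusted p = 0.0974 with the gene length trend removed) and Klrb1c at 0.02 (SE 0.137, edgeR adjusted p = 0.955). Cytotoxic granule genes were lower in 4 of 18 cases and higher in 1 (9 and 1 adjusted over the list alone), with Prf1 at −0.95 (SE 0.17) lower and the granule release gene Rab27a at 0.96 (SE 0.202) higher, and Gzmb at −1.58 (SE 0.449, edgeR adjusted p = 0.0515). Effector cytokine and chemokine genes were lower in 5 of 14 cases (5 adjusted over the list alone), including Ccl4 at −3.07 (SE 0.428) and Xcl1, a chemokine gene for cross-presenting dendritic cells, at −2.39 (SE 0.336). In the activation list 6 of 19 were lower and 1 higher (10 and 1 adjusted over the list alone). They included Tnfrsf9, the gene of the costimulatory receptor 4-1BB, at −2.24 (SE 0.405) and the receptor gene Slamf7 at −1.09 (SE 0.174). Migration and adhesion genes were lower in 10 of 23 cases and higher in 1 (11 and 3 adjusted over the list alone), again with Ccr2 at −0.83 (SE 0.125) and Itgb7 at −0.61 (SE 0.112). These 5 lists passed camera (adjusted p from 1.29e-05 to 0.00152), and none did with an estimated correlation (adjusted p from 0.141 to 0.175).

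T cell genes were higher in 4 of 20 cases and lower in 1 (4 and 1 adjusted over the list alone). Examples were Cd6 at 1.70 (SE 0.378) higher and Cd247, the zeta chain shared by T cell and NK receptors, at −0.70 (SE 0.122) lower. Group 2 and 3 innate lymphoid genes were higher in 3 of 14 cases (3 adjusted over the list alone), with Rora at 1.94 (SE 0.331) and Tmem176a at 1.52 (SE 0.304), and neutrophil genes in 4 of 6 (4 adjusted over the list alone), with Csf3r at 2.76 (SE 0.827) and S100a9 at 9.16 ± 8.95 against 0.208 ± 0.343 CPM. The B cell list was lower by camera with 1 of 30 genes called, the light chain gene Iglc2 at −1.61 (SE 0.484; 0 adjusted over the list alone), and Cd79a stood at −0.98 (SE 0.403, edgeR adjusted p = 0.148). The camera adjusted p values of these lists were 0.000832, 0.00101, 0.000761 and 0.0068, and the adjusted p values with an estimated correlation were 0.205, 0.154, 0.147 and 0.664. Cd3e stood at 0.93 (SE 0.351, edgeR adjusted p = 0.124), Lyz2 at 0.40 (SE 0.391, edgeR adjusted p = 0.644; 1 of 21 macrophage and monocyte genes higher, Vcan at 4.77, and 2 lower, Ccr2 and Ctsd at −0.56; 1 and 3 adjusted over the list alone; camera adjusted p = 0.999) and Pdcd1 at 4.07 (SE 1.33, edgeR adjusted p = 0.0632). The immunoglobulin gene Ighg1 had the largest fitted difference among the genes named here (−9.22, SE 2.33), and it rested on lymphatic replicate 4, at 55.0 CPM, where the other lymphatic libraries had 0.355 to 1.06 CPM.

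Of the 34 lists, 18 passed camera between the models, 3 higher and 15 lower in the hematogenous group, 0 with an estimated correlation and 19 with fry. The number of changed genes was 620 without lymphatic replicate 2, 620 without hematogenous replicate 3 and 811 without hematogenous replicate 1, against 2913 with voom quality weights. Other scalings changed the balance of directions: 47.4% of calls were higher with DESeq2 size factors (624 higher, 693 lower), 52.3% with upper-quartile scaling (680 and 619) and 55.8% with library size alone (744 and 590), against 33.1%, and the last moved the median log2 fold change of all genes from −0.01 to 0.10. The B cell list was lost without lymphatic replicate 1 or hematogenous replicate 2 (camera adjusted p = 0.646 and 0.105). The call of Ighg1 was lost without lymphatic 4 or any hematogenous library (highest edgeR adjusted p = 0.178), that of S100a9 without lymphatic 1, 2 or 3 or hematogenous 2 or 3 (highest edgeR adjusted p = 0.166) and that of Fosb without lymphatic 1 or 2 or hematogenous 1, 2 or 3 (highest edgeR adjusted p = 0.0872). Csf3r was lost without any lymphatic library or hematogenous 2, 3 or 4 (highest edgeR adjusted p = 0.152), Itga2b without any lymphatic library, hematogenous 1, 2 or 3 or tumor-free 3 (highest edgeR adjusted p = 0.172), and Spp1 without lymphatic 2 or 3, hematogenous 1, 2 or 3 or tumor-free 2 (highest edgeR adjusted p = 0.101). Cdc6 was lost without any library but tumor-free 2 and hematogenous 4 (highest edgeR adjusted p = 0.162), and Iglc2 without any but tumor-free 1, 2 and 4 and lymphatic 3 (highest edgeR adjusted p = 0.237), and Vcan without lymphatic 2 or hematogenous 4 (highest edgeR adjusted p = 0.0699). The B cell covariate ended the calls of Cdc6, Ighg1, Iglc2, S100a9 and Csf3r, and removal of the gene length trend those of Ncr1, Itga2b, Cdc6 and Iglc2. Cdc6 and Iglc2 were lost with each other scaling, Csf3r and Iglc2 at equal depth, and Spp1, Ighg1 and Iglc2 without the filter on low counts. Cdc6 was also lost with DESeq2 and in the fit of the compared groups alone, Ighg1 with voom quality weights and Itga2b without robust estimation. The replicate block ended the calls of Fosb, Csf3r, Itga2b, Spp1 and Iglc2 (edgeR adjusted p = 0.0509, 0.0751, 0.0728, 0.163 and 0.067).

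Both tumor models shared part of their difference from tumor-free nodes. Genes called in the same direction in both numbered 253, of which 206 were higher and 47 lower, and 3 were called in opposite directions. Slfn5, Oas2, Gbp9, Fos, Dusp1, Jun, Myb, Cd69 and Tigit, an inhibitory receptor gene chosen after its values were seen, at log2 fold changes of 1.51 and 1.77, were among the higher ones, and Nrarp, at −1.88 and −2.33, among the lower ones. The Nrarp call in the lymphatic model was lost without tumor-free 4 or lymphatic 1, 2 or 4 (highest edgeR adjusted p = 0.0998). Independent lists of these sizes would share 35.4 higher and 4.60 lower genes. Both comparisons used the same tumor-free libraries, and 20 simulations of unchanged groups against them called at most 1 gene, too few for a chance count of shared genes. They gave a median correlation of log2 fold changes of 0.516 and a median covariance of 0.202, against an observed correlation of 0.789 and covariance of 1.08. With the tumor-free libraries divided 2 and 2 between the comparisons, the 6 possible divisions gave 62 to 136 shared genes, a covariance of 1.16 to 1.46 and a correlation of 0.267 to 0.332. The divided fits held 17588 to 17604 genes against 16016, as the filter kept more low genes. Their covariance and correlation therefore cannot be set directly against the values above. The count of shared genes was 134 without lymphatic replicate 4, 151 without lymphatic replicate 1, 153 without tumor-free replicate 2 and 446 without tumor-free replicate 3, and 92 with the B cell covariate and 458 with DESeq2. Of the 446 genes 401 were higher, with the tumor-free library that had reads on most genes left out. The low detection in tumor-free replicates 1, 2 and 4 enters both comparisons in every division. The simulations drew all libraries from the same expression profile. Neither can therefore tell a shared tumor effect from this difference in detection, which stays open for part of the sharing.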

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

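The tests of the 3 patterns weighed here were chosen only after the results were seen. Oxidative phosphorylation genes were lower in the hematogenous libraries, with a median log2 fold change of −0.56 against tumor free and 20 of 36 called lower (camera adjusted p = 7.62e-14 at the preset correlation, but adjusted p = 0.33 with an estimated correlation). With the gene length trend removed the median was −0.53 with 21 genes called lower (camera adjusted p = 2.62e-11 at the preset correlation), which argues against length bias as the whole cause. Without hematogenous replicate 1, the library with most reads outside annotated features, the median was −0.46 with 13 called lower (camera adjusted p = 1.03e-12 at the preset correlation), which argues against that library alone as the cause. A difference in RNA quality across the whole hematogenous group stays open, because its share of reads assigned to genes was 62.0% ± 4.57 against 68.3% ± 2.32 in tumor-free libraries. A lower respiratory program in NK cells of this model may also hold and was not tested.

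NK receptor genes were lower in the hematogenous libraries, with a median of −0.46 against tumor free (camera adjusted p = 1.58e-09 at the preset correlation, but adjusted p = 0.0521 with an estimated correlation). Removal of the length trend left a median of −0.50 with 11 genes called lower (camera adjusted p = 3.59e-08 at the preset correlation), which argues against length bias as the whole cause. Dilution by cells that express none of the receptor genes would move them all by a common amount. Of the variation in fold change between 31 genes of the NK receptor and Ly49 lists, 89.99% lay beyond their standard errors (chi-square heterogeneity p = 2.9e-46). This argues only against dilution by such cells as the whole cause. Cells that express some of these genes would give unequal falls, what other cells expressed was not measured, and Ly49 reads can be split among paralogs. A gain of other cells therefore stays open. Lists of T cells, group 2 and 3 innate lymphoid cells, neutrophils, dendritic cells and erythroid cells passed camera as higher (adjusted p = 0.0173, 0.00216, 0.012, 0.0342 and 0.0162). None did with an estimated correlation (adjusted p = 0.55, 0.33, 0.383, 0.33 and 0.447). At equal depth the neutrophil, dendritic cell and erythroid lists were lost (camera adjusted p = 0.0706, 0.0513 and 0.0706). The T cell, dendritic cell and erythroid lists were each lost without some single library (highest camera adjusted p = 0.0731, 0.0719 and 0.0736). A difference in RNA quality across the hematogenous group stays open as for oxidative phosphorylation, by the same shares of reads assigned to genes, and a changed NK cell state with this route of spread may also hold and was not tested.

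Immediate early genes were higher in the lymphatic libraries, which were also the deepest group (camera adjusted p = 1.01e-22 at the preset correlation, but adjusted p = 0.0743 with an estimated correlation). At equal depth 15 of the 15 called genes, or 100%, were still called, which argues against depth. If handling before lysis were the cause, heat shock genes would rise with the early-response genes, and they did, with a median of 0.73 and 3 of 6 called, beside 1.18 and 12 of 18. The same genes were lower in the hematogenous than in the lymphatic libraries, with medians of −1.01 for heat shock and −0.90 for early-response genes. Handling therefore stays open, since the labels give no handling times per group, and stimulation of NK cells in the node may give the same values and was not tested.

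Single libraries far from the other 3 of their group were sought in 460 groups of values, from log2(CPM + 1) of 150 named genes and from 5 library measures. The measure was the gap to the nearest library divided by the range of the group, held against the 95% critical value of Dixon's test. It was passed in 35 groups, and in 26 of them the library was the highest. A rate of 1 in 20 would give 23, but that rate holds for independent, normally distributed values. These genes came from the same 12 libraries, and in some groups all but 1 library had 0 counts. The 23 is therefore only a rough mark and not a chance level. Tumor-free replicate 3 held 13. It was highest for Atf3, Bend4, Csf3r, Flt3 and S100a9 (each 1, as the other libraries had 0 counts), Fasn (0.938), Pecam1 (0.913), Ikzf2 (0.868) and Pax5 (0.866). It was lowest for Psmb10 (0.930) and Map1b (0.904). Its gene counts (0.900) and its genes detected at equal depth (0.914) also stood apart. Lymphatic replicate 2 held 8 and was highest in each, for Hspa5 (0.981), Cpt1a (0.927), Xcl1 (0.910), Ran (0.889), Hspa8 (0.887), Nr4a1 (0.876), Mcm3 (0.849) and Slc3a2 (0.840). Hematogenous replicate 1 held 3, as the lowest for Egr1 (0.887) and the highest for Zfp683 (0.935) and Ighg1 (1). Lymphatic replicate 4 was highest for Ighg1 (0.887) and Kif11 (0.872). Tumor-free replicate 1 was highest for Gzmb (0.930) and lowest for Tgfb3 (0.917) and Dusp1 (0.872). Hematogenous replicate 4 was highest for Gbp9 (0.912) and hematogenous replicate 3 for Klrk1 (0.854). Lymphatic replicate 1 was lowest for Bak1 (0.898) and lymphatic replicate 3 for Cd68 (0.982), Tcf4 (0.931) and Pou2f2 (0.833).

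The models moved 3 genes in opposite directions from tumor free, each called in both. Because they were chosen by these opposite calls against the same tumor-free libraries, their adjusted p in the direct comparison is not independent evidence of a difference. Pik3ap1, an adaptor gene of PI3 kinase signalling, was at 0.67 in the lymphatic and −0.42 in the hematogenous model, a difference of −1.09 (edgeR adjusted p = 0.000149). Ehd4, a gene of endocytic recycling, was at 0.91 and −0.75, a difference of −1.66 (edgeR adjusted p = 0.000141). Cirbp, which encodes a cold-inducible RNA-binding protein, was at −0.62 and 0.51, a difference of 1.12 (edgeR adjusted p = 0.000168). Lists of G1 and S genes, glycolysis and MYC targets passed camera as higher in the lymphatic and lower in the hematogenous model, and they differed between the models at camera adjusted p = 4.89e-12, 4.4e-07 and 1.73e-09. These lists too were chosen by their opposite directions, so these p values are not independent evidence. With an estimated correlation none passed, at adjusted p = 0.147, 0.147 and 0.205 between the models, 0.463, 0.546 and 0.622 in the lymphatic model and 0.516, 0.417 and 0.601 in the hematogenous model. The lymphatic glycolysis call was also lost at equal depth (camera adjusted p = 0.12) and without any of 7 libraries (tumor-free 3 and 4, lymphatic 2, hematogenous 1 to 4; highest camera adjusted p = 0.316), and the lymphatic MYC call without tumor-free replicate 3 or lymphatic replicate 2 (camera adjusted p = 0.0758 and 0.732).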

How the results depend on the processing

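Equal depth and removal of the gene length trend were chosen only after the data were seen. Over all alternatives, 6148 values of called named genes kept their direction and call and 627 lost the call, with none reversed, leaving out 5 without an adjusted p from DESeq2. Calls of named genes held without each library in turn for 37 of 59 genes in the lymphatic, 80 of 97 in the hematogenous and 65 of 87 in the direct comparison. For lists that passed camera, 812 values kept the call and 100 lost it. Without single libraries the lymphatic model gave 255 to 634 genes, the hematogenous model 1760 to 3202, the direct comparison 620 to 1572 and the overlap 134 to 446. Lists passing ranged from 13 to 18, 13 to 17 and 17 to 21. DESeq2 called 729 genes in the lymphatic model and 458 shared genes, and voom with quality weights 2913 between the models. The B cell covariate left 207 and 1507 genes for the lymphatic and hematogenous models and 92 shared, but gave 1660 between the models. Removal of B cell and immunoglobulin genes gave 437, 2633 and 1413 genes and 252 shared. A 2-fold minimum left 243, 893, 346 and 122 shared, and an adjusted p under 0.01 left 195, 1109, 477 and 71 shared, as stricter thresholds must give fewer. With an estimated correlation 2, 0 and 0 lists passed camera, and 7 passed fry for the hematogenous model. Divided tumor-free libraries, with fewer samples per fit, gave 104, 62, 94, 78, 136 and 80 shared genes. No gene that changed sign was called. With voom quality weights the hematogenous model gave Cd79a −0.27 and Lyz2 0.25. The B cell covariate gave Prf1 0.17, Cd3e −0.15 and Lyz2 0.17 in the lymphatic model, Ifng 0.11, Cd79a −0.37 and Lyz2 0.25 in the hematogenous model, and Klrb1c −0.0688 between them. Without single libraries, Prf1 ran from −0.34 to 0.0053 in the lymphatic model and Klrb1c from −0.047 to 0.19 between the models. In the hematogenous model Ifng ran from −0.28 to 0.10, Mki67 from −0.35 to 0.018, Cd79a from −0.14 to 0.54 and Lyz2 from −0.24 to 0.22. Apart from the stricter thresholds and divided libraries, the cause was not tested. With the mean of each group taken out, same-numbered libraries of different groups correlated at −0.07 to 0.06 over 12 pairs. Differently numbered libraries of different groups correlated at −0.10 to 0.15 over 36 pairs. This gave no sign that replicate numbers pair the samples, but does not exclude it. The replicate block gave 362, 2518 and 1439 genes, 208 shared genes and 18, 15 and 20 lists. Depth limits low genes most in the tumor-free group. At equal depth the lymphatic model lost glycolysis and stroma (camera adjusted p = 0.12 and 0.377), the hematogenous model cholesterol, dendritic, neutrophil and erythroid lists (0.104, 0.0513, 0.0706 and 0.0706) and the direct comparison B cell and neutrophil lists (0.0774 and 0.0579).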

Other observations

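The search for genes without reads in 1 group and the genes named for it here were chosen only after the results were seen, while the other splits of the samples were fixed before the data were examined. In the hematogenous model, genes of fatty acid use, apoptosis and hypoxia moved without a common direction. Cpt1a, the gene of the enzyme that admits long-chain fatty acids to mitochondria, rose from 85.8 ± 21.6 to 181 ± 18.7 CPM (n = 4 per group; log2 fold change 1.08, SE 0.154, edgeR adjusted p = 0.000178) and stood 1.37 (SE 0.154) above the lymphatic model. In its list of 17 lipid uptake and storage genes 3 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.897), with the cholesterol exporter genes Abca1 at 0.77 (SE 0.147) and Abcg1 at −0.57 (SE 0.136). Its median (−0.23) and mean (0.38) differed in sign. Bcl2l11, which encodes the pro-apoptotic protein BIM, rose from 155 ± 34 to 416 ± 152 CPM (1.43, SE 0.221, edgeR adjusted p = 0.000402), while the anti-apoptotic gene Bcl2l1 stood at −1.20 (SE 0.2) and the pro-apoptotic gene Bak1 at −1.12 (SE 0.198). Of 23 apoptosis genes 3 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.897). Of 17 hypoxia genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.293), with the histone demethylase gene Kdm3a at 0.57 (SE 0.143) and the glucose transporter gene Slc2a1 at −0.61 (SE 0.158). The Kdm3a call was lost with the gene length trend removed (edgeR adjusted p = 0.103), and the Slc2a1 call with voom quality weights (adjusted p = 0.0756) and with the B cell covariate (edgeR adjusted p = 0.0561).

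State lists that did not pass in the hematogenous model also held called genes. Slamf6, a self-binding receptor gene of lymphocytes, rose by 1.34 (SE 0.172) in an activation list with 4 of 19 higher and 2 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.953). Ikzf2, the gene of the transcription factor Helios, rose by 1.28 (SE 0.182) and Thy1 stood at −0.79 (SE 0.129) in the list of immature NK cell genes, with 4 of 16 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.597). In the list of mature NK cell genes 3 of 13 fell (3 adjusted over the list alone; camera adjusted p = 0.423), with Spn at −0.42 (SE 0.109), while its median (0.13) and mean (−0.06) differed in sign. Xcl1 at −1.54 (SE 0.328) and Tnfsf14 at −0.70 (SE 0.163) were lower in a list of effector cytokines and chemokines with 4 of 14 lower (4 adjusted over the list alone; camera adjusted p = 0.0524), whose median (−0.26) and mean (0.04) differed in sign. Between the models, Nr4a2 at −2.56 (SE 0.321) and Nr4a1 at −2.47 (SE 0.401) were lower in the inhibitory receptor list, with 8 of 25 lower and 2 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.0646). In the lymphatic model the interleukin-10 receptor gene Il10ra rose by 0.99 (SE 0.129) as the single called gene of the 22 in the cytokine receptor list (2 adjusted over the list alone; camera adjusted p = 0.248). Genes of tissue-resident innate lymphoid cells went both ways in the hematogenous model, 4 higher and 7 lower of 23 (6 and 8 adjusted over the list alone; camera adjusted p = 0.125). Itga1 stood at 30.5 to 45.6 CPM there against 55.4 to 77.6 CPM in the tumor-free libraries. The ranges of Zfp683 overlapped, at 5.79 to 13.5 against 6.66 to 28.4 CPM. Between the models the list did not pass, with 5 higher and 4 lower (camera adjusted p = 0.2). Of 10 plasma cell and germinal centre genes 2 rose in the lymphatic model (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0676). The calls of these genes, Bcl6 and Irf4, were lost with the B cell covariate (edgeR adjusted p = 0.448 and 0.179). They were also lost in the fit of the compared groups alone (edgeR adjusted p = 0.0514 and 0.0519). None of 14 MHC class II presentation genes was called by edgeR in any comparison (camera adjusted p = 0.15, 0.953 and 0.211). Macrophage and monocyte genes had medians of −0.21 and −0.22 and means of 0.32 and 0.58 in the lymphatic and hematogenous models. The lowest camera adjusted p among lists that did not pass was 0.0676 for the lymphatic model, 0.0524 for the hematogenous model and 0.0573 between the models.

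Map1b, a gene of a microtubule-associated protein, had 26 to 102 reads in each of the 8 tumor-free and hematogenous libraries, 453 in all, and 0 among 125188781 counts of the lymphatic libraries, at least 182-fold lower with 3 reads over the group as the floor. It was the single gene of this kind, with reads in every other library, none in the group and at least 20 expected, for the lymphatic group. The hematogenous group also had 1 and the tumor-free group 94, and among all 495 choices of 4 libraries those that mixed groups gave up to 148.

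Each comparison of 4 against 4 libraries allows 35 splits, and in each of the 3 comparisons 1 split, the real one, gave as many changed genes. Against tumor free the real split gave 439 genes for the lymphatic model where the highest of the others gave 0, and 2625 genes for the hematogenous model where the highest of the others gave 3. Between the models it gave 1417 where the highest of the others gave 2. Ranking first of 35 is the most extreme outcome that the design allows, which argues against a chance division of the libraries but does not exclude it. Mixed splits hold the group difference as spread within groups, which lowers their counts. The splits also cannot tell the groups from depth, detection or RNA quality that follow them.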
